A study of Desulfitobacterium hafniense Y51 with 10 samples.

How the data were processed

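RNA of the bacterium *Desulfitobacterium hafniense* Y51 was measured on 10 one-colour Agilent arrays. Per the labels' protocols, 5 µg of total RNA was reverse-transcribed, labelled with Cy3 and hybridised, 1 sample to 1 array. The labels place 3 arrays in fumarate-limited chemostats, 2 in lactate-limited chemostats, 3 in ammonium-deprived chemostats and 2 in batch cultures. They do not state that arrays of 1 group came from separate cultures, so the p-values measure the spread between these samples. Ammonium-deprived replicates 2 and 3 have the same medium, flow and volume in the labels, and averaging them into 1 replicate was an alternative fixed before the data were examined.

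The array design, per the series description, covers the genomes of the strains DCB-2 and Y51. The scanner files hold 21947 distinct probes, each spotted 2 times, with 11694 named SH and 10253 named U. These codes carry no gene names. Per the file headers, the scanner values are spot intensity and local background intensity from Agilent Feature Extraction 10.7.3.1. It was run with a two-colour protocol, so the processed green intensity was dye-normalised against a red channel that held no sample, per the file headers. The authors also deposited a table of log2 values for 9252 features, of which 4824 are locus tags and 4428 are regions of the Y51 chromosome. A comment in that table calls its values log2 ratios of chemostat to batch, yet the batch arrays have columns of their own and all values lie between 2.65 and 18.4. The deposited values were therefore read as log2 levels, and their scaling, their centring and the filters behind them are not given in the sources used here. The column medians lay between 8.81 and 9.02. The 45 correlations between pairs of arrays, taken from the table and from the scanner files, correlated with each other at r = 0.97 over pairs, which share arrays and are not independent.

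The design fixed beforehand takes gene values from the scanner files. Their probe codes name no gene, so the locus tags of the authors' deposited log2 table became the main values, and the scanner files as designed became an alternative. For that alternative, green mean intensity was background-corrected with normexp (offset 50) and scaled to the 75th percentile of each array. Spots marked as outliers were left out. Probes well above background on at least 2 arrays were kept and the probes of a target averaged, which left 7776 targets. Tags and targets were also compared by their values over the 10 arrays. A total of 1055 tags followed a target at r above 0.97, and of the 915 matched to SH targets, 65.6% of successive matches lay within 10 target numbers of each other, against at most 1.42% in 200 shuffled orders. These matches were used to compare positions and not to name genes.

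All 4824 locus tags were fitted in 1 limma model with the group as its only term, so that the 4 groups shared 1 estimate of the spread (6 residual and 4.56 prior degrees of freedom). The 6 comparisons were contrasts of group means, two-sided, with Benjamini-Hochberg adjustment over the tags of each contrast and a threshold of 0.05. The 1136 regions with a start of their own were fitted in the same way, apart from the tags. A further 3292 regions share the start 101009 and have ends from 101127 to 104432, of which 99.8% of sorted neighbours differ by 1 base. The spread of level differences between such neighbours was 94.0% of that between random pairs, so their printed coordinates were not used as positions.

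The rule for single genes, fixed before the data were examined, took genes past the threshold whose 2 groups did not overlap, ordered by log2 fold change. The files do not pair locus tags with gene names, so at most 2 tags that rose and 2 that fell are printed for each comparison, by that order. For the same reason the gene lists fixed beforehand (nitrogen fixation, dehalogenation, fumarate reduction and others), their camera tests and the genes fixed by name could not be looked up and were not run. Runs of at least 4 consecutively numbered tags called in 1 direction were counted against 10000 shuffles of the calls over the tags. This count was chosen after the values were seen.

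The slides held 5 arrays each. Slide 1 held fumarate-limited replicate 1, ammonium-deprived replicates 1 and 2 and both lactate-limited arrays. Slide 2 held ammonium-deprived replicate 3, both batch arrays and fumarate-limited replicates 2 and 3. Slide was tested as a fixed block, as a random block and by fits within 1 slide. Other alternatives were the replicate number as a block, fits of 2 groups alone, an intensity trend, leaving out each array, and the other signal, scalings, filters and probe summary of the scanner files. Added after the data were seen were 3 scalings of the table, leaving out the 3 dimmest arrays, array weights and only genes above the median level.

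The fit was tested on simulated data of 4824 genes with 50 changed genes per size in 5 data sets. For fumarate-limited against batch it recovered 3.20% of genes changed by 1 log2 unit, 44.4% at 2 units and 97.6% at 4 units. For lactate-limited against batch it recovered 31.2% at 2 units and 94.4% at 4 units. For ammonium-deprived against fumarate-limited it recovered 54.8% at 2 units and 97.6% at 4 units. False calls made up 2.73% to 5.91% of calls over the 6 comparisons. The simulated noise of a gene had the same spread on every array. In the data, the SD of deviations from the group mean ran from 0.265 on the batch arrays to 0.879 on fumarate-limited replicate 3. These rates therefore need not hold for the data.

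Precision is limited by the number of arrays. The 75th percentile of green spot intensity lay between 1174 and 3688 on 7 arrays. It was 236 on ammonium-deprived replicate 3, 338 on fumarate-limited replicate 3 and 365 on ammonium-deprived replicate 2. Between 35.7% and 69.4% of spots were well above background and 0 were saturated. Spots marked as outliers numbered 3480 and 2564 on the batch arrays and 1836 on fumarate-limited replicate 2, against 78 to 602 on the others. The deposited table holds no detection flags, so low levels in it can be bounds. Tools were R 4.3.3, limma 3.58.1, data.table version 1.17.8, statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.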

Results

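Transcript levels of *Desulfitobacterium hafniense* Y51, an anaerobic bacterium, were measured on 10 arrays from 4 kinds of culture fed lactate as electron donor and fumarate as electron acceptor. Batch cultures (n = 2) held 25 mM fumarate and 20 mM lactate. The fumarate-limited chemostats (n = 3) received 25 to 35 mM fumarate with 20 to 30 mM lactate, the lactate-limited ones (n = 2) 60 mM with 20 mM, and the ammonium-deprived ones (n = 3) 60 to 65 mM with 40 mM. Medium flow and volume gave dilution rates of 0.0177 to 0.0203 per h. The values are log2 levels of 4824 locus tags, called genes here, and of 1136 regions of the Y51 chromosome. Median levels were 10.39 for genes and 7.34 for regions.

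The 4 groups did not separate equally. The first 2 principal components held 35.5% and 24.2% of the variance, and the batch arrays lay at 67.5 and 74.8 on the first one, against -40.9 to -1.69 for the 8 chemostat arrays. The batch arrays correlated at 0.970 over genes, which are not independent replicates. Ammonium-deprived replicates 2 and 3 correlated at 0.952 with each other, and at 0.832 and 0.796 with replicate 1, which correlated at 0.918 with fumarate-limited replicate 2. Fumarate-limited replicate 3 correlated at 0.561 to 0.793 with the other arrays.

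**Figure D1:**
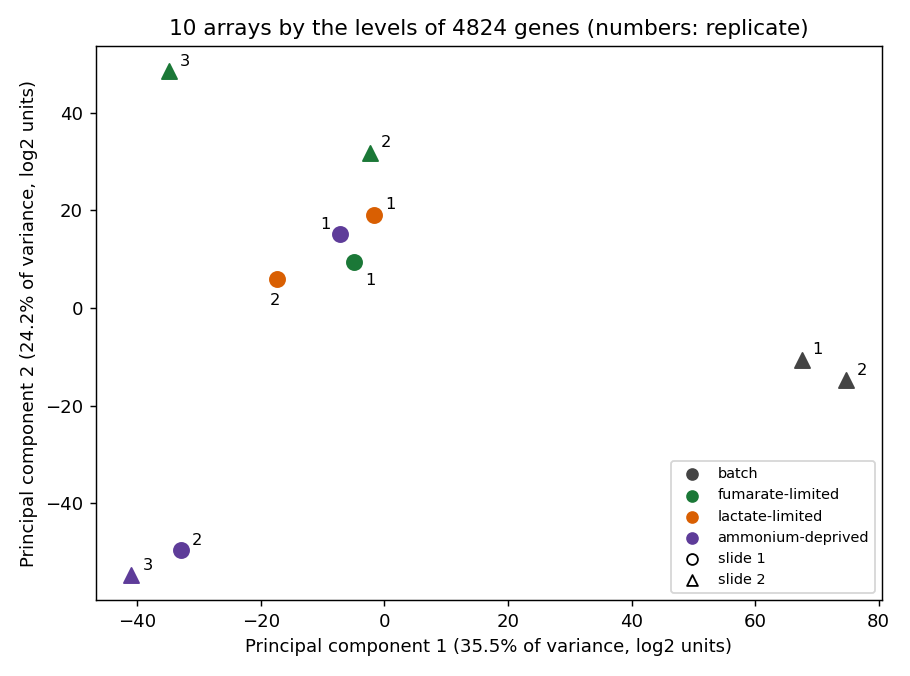
Scores of the 10 arrays on principal components 1 (x axis, 35.5% of variance) and 2 (y axis, 24.2%) of the log2 levels of 4824 genes, with colour for the group, shape for the slide and the replicate number beside each point. The batch arrays lie at 67.5 and 74.8 on component 1 and the chemostat arrays at -40.9 to -1.69.

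The comparison of fumarate-limited chemostats with batch asked how chemostat growth on limiting electron acceptor differed from batch growth. It called 610 of 4824 genes, 193 higher and 417 lower in the chemostats. DSY2248 rose most, from 8.87 ± 0.26 (SD, n = 2) to 16.53 ± 0.30 (SD, n = 3), a log2 fold change of 7.65 (SE 0.52, limma adjusted p 5.67e-05). DSY3940 rose by 7.38 (SE 0.42, limma adjusted p 1.71e-05). Neither rise was particular to fumarate limitation. Against batch, DSY2248 rose by 6.97 in lactate-limited and 7.73 in ammonium-deprived chemostats, and DSY3940 by 7.49 and 7.43. DSY2276 fell by 6.75 (SE 0.63), from 15.15 ± 0.39 to 8.40 ± 0.47, and DSY4709 fell by 5.19 (SE 0.63). Among the changed genes, 15 were at least 32-fold higher and 2 at least 32-fold lower. Of the changed genes, 123 (20.2%) lay in 22 runs of consecutively numbered tags, 20 of them lower in the chemostats. The longest run, DSY3009 to DSY3019, had a median change of -2.11 and was chosen after its values were seen.

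All 610 genes had arrays that did not overlap between the groups. Over all genes this held for 53.6%, where chance gives 20%. The median change of all genes was -0.19 on the log2 scale, and the split depended on scaling: 276 higher and 345 lower after median scaling of the table, 326 and 316 after 75th percentile scaling. The scanner files gave 186 higher and 566 lower of 7776 probe targets, and 11 higher and 1049 lower with median scaling. With slide as a fixed block 638 genes changed (152 higher, 486 lower), and slide 2 alone gave 242 (87 higher, 155 lower). The count was 82 without batch replicate 1, 29 without batch replicate 2 and 297 without fumarate-limited replicate 2. It rose to 1094 without the 3 dimmest arrays and 1844 with array weights.

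Lactate-limited chemostats differed from batch in 315 genes, 187 higher and 128 lower. DSY4438 rose by 8.38 (SE 1.16), from 7.66 ± 0.05 to 16.05 ± 0.74 (SD, n = 2 each), with a limma adjusted p of 0.00177. DSY0565 rose by 7.63 (SE 1.02). In fumarate-limited chemostats against batch, DSY4438 rose by 5.55 and DSY0565 by 6.83. DSY2276 and DSY4709, the same tags that fell most in the fumarate-limited chemostats, fell by 4.65 (SE 0.69) and fell by 4.34 (SE 0.69). At least 32-fold changes numbered 40 higher and 0 lower, of 187 and 128 called by limma. A run of 11 tags, DSY1709 to DSY1719, was 45.2-fold higher in the median and was chosen after its values were seen. In all, 88 of the 315 genes (27.9%) lay in 16 runs.

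The groups did not overlap for any of the 315 genes, nor for 64.8% of all genes, where chance gives 33.3%. The median change of all genes was -0.12. The scanner files gave 222 higher and 331 lower of 7776 targets, a split with more lower than higher, and 79 higher and 206 lower with median scaling. With slide as a fixed block 109 genes changed (63 higher, 46 lower), and 104 of these were among the 315. No slide held both groups, so no count within 1 slide could be made. The count was 111 without batch replicate 1, 85 without batch replicate 2 and 78 without lactate-limited replicate 2. It rose to 979 with these 2 groups alone, 1041 without the 3 dimmest arrays and 1303 with array weights.

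Ammonium-deprived chemostats differed from batch in 597 genes, 277 higher and 320 lower. DSY4438 rose by 8.31 (SE 1.05), to 15.97 ± 0.21 (SD, n = 3), close to its level in the lactate-limited chemostats. DSY4271 rose by 7.89 (SE 0.43), from 8.23 ± 0.14 (SD, n = 2) to 16.12 ± 0.44 (SD, n = 3), with a limma adjusted p of 5.36e-06. DSY2707 fell by 5.17 (SE 0.50) and DSY4710 by 4.85 (SE 0.64). At least 32-fold changes numbered 56 higher and 1 lower. Runs held 140 of the 597 genes (23.5%), 25 runs in all, the longest of 16 tags.

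All 597 genes had arrays that did not overlap between the groups. Over all genes this held for 51.3%, where chance gives 20%. The median change of all genes was -0.25, and 75th percentile scaling of the table turned the split to 333 higher and 256 lower. The scanner files gave 273 higher and 460 lower, and 121 and 1014 with median scaling. With slide as a fixed block 432 genes changed (160 higher, 272 lower), and slide 2 alone gave 279 (195 higher, 84 lower), with 1 ammonium-deprived array assumed to vary like the other groups. The count was 1047 without ammonium-deprived replicate 1, 196 without replicate 2, 179 without replicate 3, 123 without batch replicate 1 and 67 without batch replicate 2. It was 197 with replicates 2 and 3, whose labels are the same, as 1, 2145 with array weights and 394 without the 3 dimmest arrays, a fit that leaves replicate 1 alone in its group, assumed to vary like the others.

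**Figure D2:**
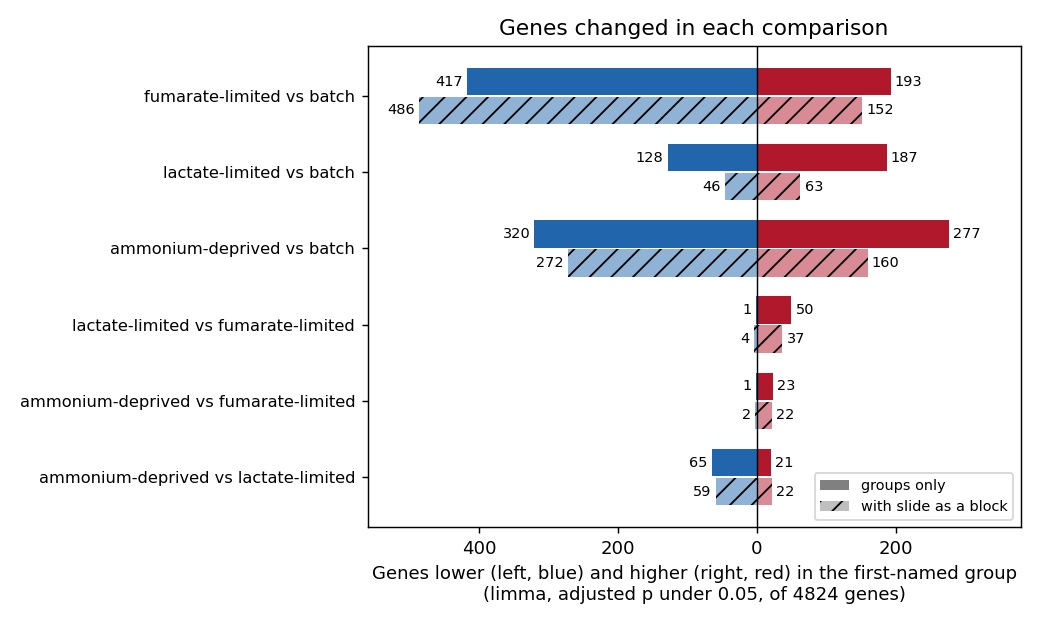
Number of genes lower (left, blue) and higher (right, red) in the first-named group of each comparison, by limma at an adjusted p under 0.05, with solid bars for the fit of groups and hatched bars for the fit with slide as a block. The comparisons with batch hold 315 to 610 genes and those between chemostats 24 to 86.

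The 3 chemostat groups shared part of their difference from batch. Batch was higher than each of them for 109 genes and lower than each for 87, while simulations without effects gave 0 such genes in each of 100 data sets. Fumarate-limited and ammonium-deprived chemostats shared 121 higher and 250 lower genes, where independent lists would share 11.1 and 27.7. Fumarate-limited and lactate-limited chemostats shared 106 and 121 (7.48 and 11.1), and lactate-limited and ammonium-deprived chemostats 104 and 110 (10.74 and 8.49). The no-effect simulations gave mean overlaps of 0 to 0.01. In them the groups share the mean of each gene, so few genes can be called in any comparison. Their counts and overlaps therefore do not measure what the shared batch arrays add. Fold changes of these pairs correlated at 0.77 to 0.81 over genes (simulated 0.55 to 0.60), with covariances of 1.58 to 1.60 against a simulated 0.23. With 1 batch array for each comparison of a pair, both ways round and assumed to vary like the other groups, fold changes correlated at 0.70 to 0.78, with covariances of 1.49 to 1.56. Each pair then shared 14 to 27 higher and 5 to 13 lower genes, where independent lists would share at most 1.04 and 0.18. Runs lower in all 3 comparisons, chosen after their values were seen, were DSY0502 to DSY0505, DSY2700 to DSY2707, DSY3114 to DSY3119, DSY3880 to DSY3883 and DSY4709 to DSY4712.

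The run DSY4709 to DSY4712 fell furthest of these 5, with median log2 changes of -4.54 in fumarate-limited, -4.17 in lactate-limited and -4.53 in ammonium-deprived chemostats. In the same order, DSY2700 to DSY2707 changed by -3.07, -2.75 and -2.96, and DSY3114 to DSY3119 by -3.09, -3.09 and -2.90. DSY3880 to DSY3883 changed by -3.22, -3.21 and -2.05, and DSY0502 to DSY0505 by -3.02, -3.05 and -2.62. DSY1647 to DSY1650 lay in a run that was higher in each kind of chemostat, with median rises of 3.22 over 7 tags, 3.71 over 8 tags and 2.23 over 4 tags. These runs, too, were chosen after their values were seen.

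Lactate-limited and fumarate-limited chemostats differed in 51 genes, 50 of them higher under lactate limitation. These groups differ in the limiting substrate and in the fumarate feed, 60 mM against 25 to 35 mM. DSY3100 was 5.74 higher (SE 0.65), at 15.51 ± 0.53 (SD, n = 2) against 9.77 ± 1.16 (SD, n = 3), with a limma adjusted p of 0.00142. DSY2479 was 5.66 higher (SE 0.55). The gene that was lower, DSY0226, fell by 3.18 (SE 0.57, limma adjusted p 0.0222), and over 17 alternatives its adjusted p reached 0.595. Runs held 30 of the 51 genes (58.8%), in 5 runs: DSY1709 to DSY1718, DSY3364 to DSY3370, DSY2314 to DSY2318, DSY3098 to DSY3101 and DSY4254 to DSY4257, chosen after their values were seen. The first of these was 13.7-fold higher in the median and the last 39.4-fold.

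All 51 genes had arrays that did not overlap between the groups. Over all genes this held for 21.0%, where chance gives 20%. The median change of all genes was 0.10, and quantile scaling of the table gave 50 higher and 8 lower. The scanner files gave 44 higher and 0 lower of 7776 targets by limma, with 352 at an unadjusted p under 0.05. With slide as a fixed block 41 genes changed (37 higher, 4 lower). On slide 1, with 1 fumarate-limited array, limma called 0 genes, with 207 at an unadjusted p under 0.05, and slide 2 held no lactate-limited array. The count was 32 without lactate-limited replicate 2, 205 without the 3 dimmest arrays and 184 with array weights. The run DSY1709 to DSY1718 kept a median rise of 3.54 with slide as a fixed block, 3.39 without lactate-limited replicate 2 and 3.58 on slide 1 alone, against 3.78 in the fit reported here. Of its 10 tags, limma called 6, 5 and 0 in these 3 fits.

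Ammonium-deprived chemostats were set against fumarate-limited ones, which had a lower feed, and 24 genes differed, 23 of them higher. A single run of 16 consecutive tags, DSY4258 to DSY4273, held 66.7% of them and was chosen after its values were seen. Its median rise was 6.98 on the log2 scale, or 126-fold. DSY4267 rose by 7.87 (SE 0.39), from 6.62 ± 0.37 to 14.48 ± 0.53 (SD, n = 3 each), and DSY4271 by 7.79 (SE 0.38), both with a limma adjusted p of 2.29e-06. The gene that was lower, DSY0565, fell by 5.62 (SE 0.83, limma adjusted p 0.0083), and over 20 alternatives its adjusted p reached 1.00.

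The median level of the 16 tags was 16.21, 15.90 and 15.72 in the ammonium-deprived arrays and 8.48 to 9.87 in the 7 others. All 24 genes had arrays that did not overlap between the groups. Of all genes this held for 515, where chance gives 10% of 4824. The 75th percentile scaling of the table gave 23 higher and 4 lower, and the scanner files gave 18 higher and 0 lower by limma, with 257 at an unadjusted p under 0.05. With slide as a fixed block 24 genes changed (22 higher, 2 lower), slide 1 alone gave 16 and slide 2 alone 76 (63 higher, 13 lower). These 2 fits rest on 1 fumarate-limited array and 1 ammonium-deprived array, each assumed to vary like the other groups. The count was 367 without ammonium-deprived replicate 1 and 1062 with array weights.

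**Figure D3:**
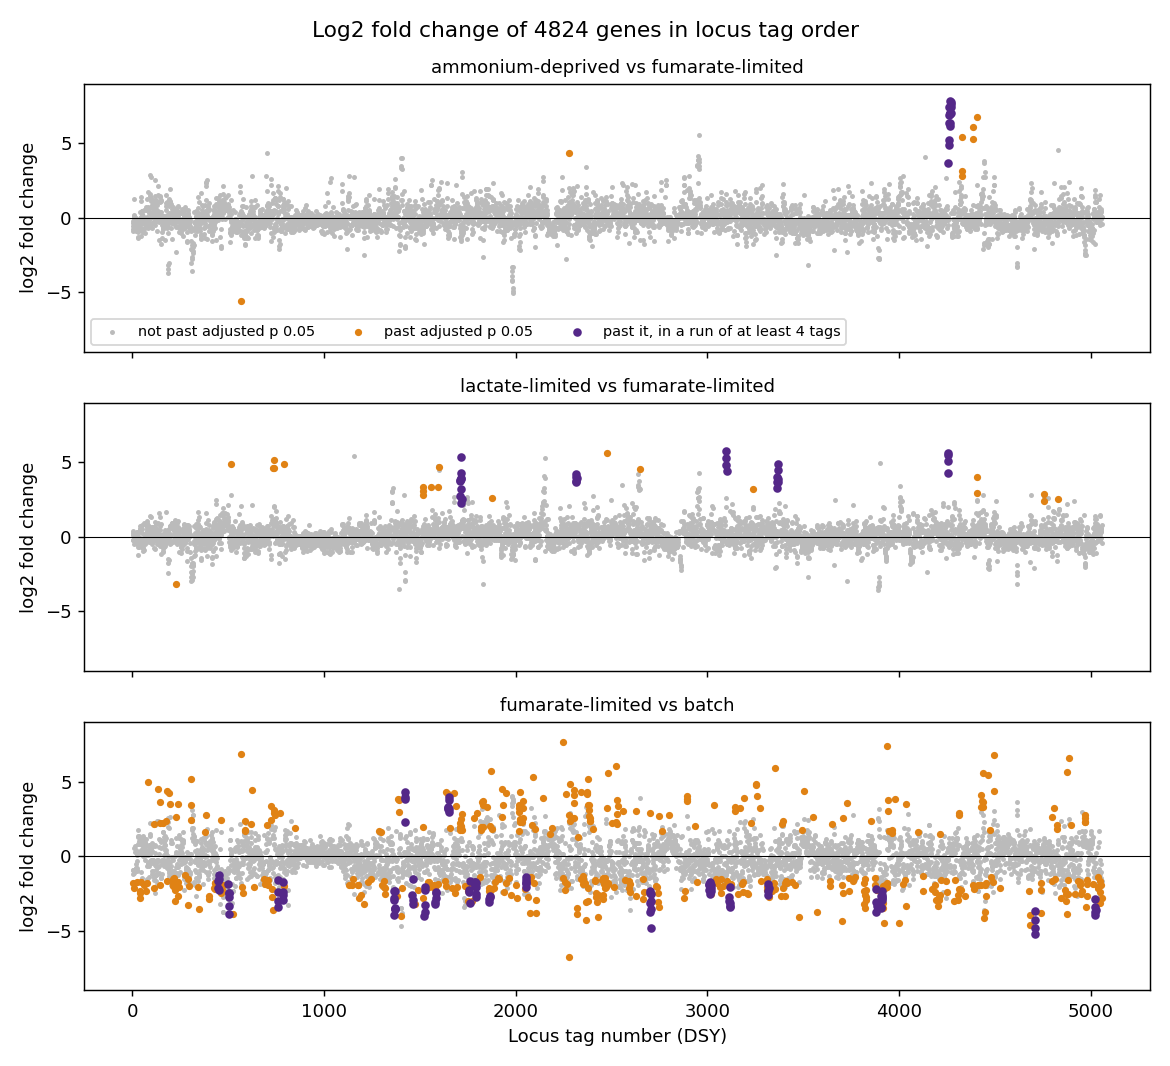
Log2 fold change (y axis) of 4824 genes by locus tag number (x axis) in 3 comparisons, with grey points for genes not past the adjusted p threshold, orange for genes past it and purple for those past it in a run of at least 4 tags. The run of 16 tags from DSY4258 stands at a median of 6.98 in the upper panel.

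Ammonium-deprived and lactate-limited chemostats differed in 86 genes, 21 higher and 65 lower under ammonium deprivation. DSY4263 and DSY4270 were each 7.36 higher (SE 0.43 and 0.48, limma adjusted p 7.71e-06 and 1.48e-05), at 15.86 ± 0.31 and 16.19 ± 0.20 (SD, n = 3) against 8.49 ± 0.15 and 8.83 ± 0.26 (SD, n = 2). DSY0565 fell by 6.41 (SE 0.93) and DSY0737 by 6.13 (SE 0.43). Runs held 47 of the 86 genes (54.7%), 6 runs in all. One of them, DSY4259 to DSY4273, was 132-fold higher in the median, and the other 5 were lower, among them DSY1709 to DSY1718, with a median change of -4.64.

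All 86 genes had arrays that did not overlap between the groups. Over all genes this held for 21.2%, where chance gives 20%. The median change of all genes was -0.10. The scanner files gave 17 higher and 60 lower. With slide as a fixed block 81 genes changed (22 higher, 59 lower), and slide 1 alone gave 45 (18 higher, 27 lower), while slide 2 held no lactate-limited array. The count was 247 without ammonium-deprived replicate 1 and 374 with array weights.

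**Figure D4:**
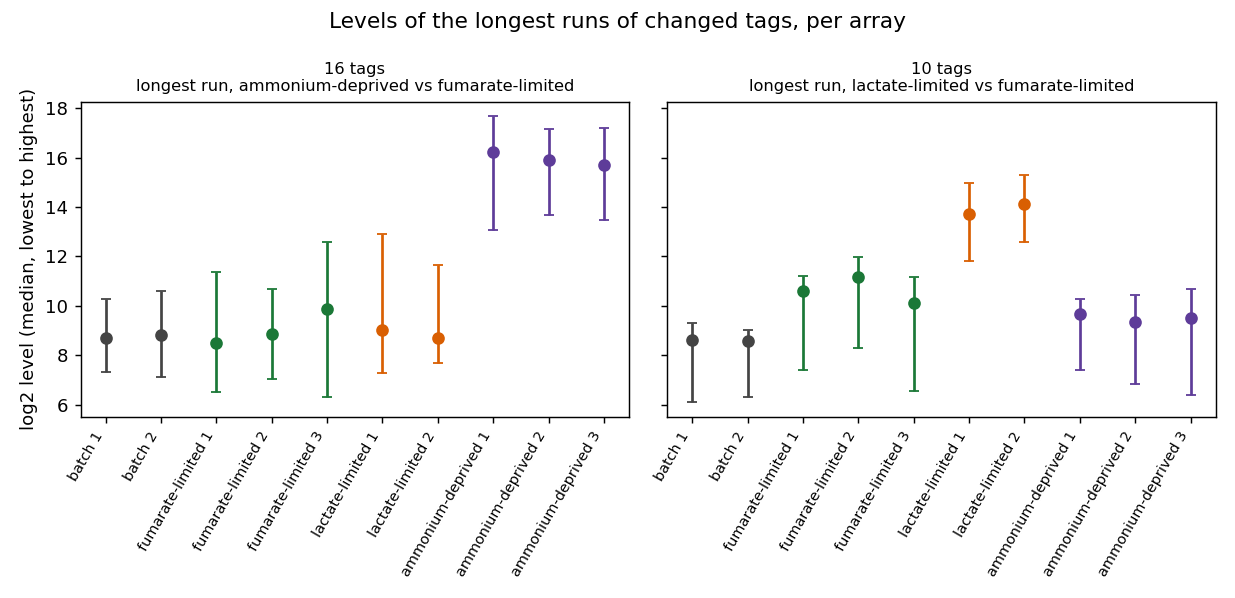
Log2 level (y axis) of the longest run of changed tags in each array (x axis), 16 tags for ammonium-deprived against fumarate-limited on the left and 10 tags for lactate-limited against fumarate-limited on the right, with points for the median of the tags and bars from the lowest to the highest tag. On the left the ammonium-deprived arrays lie at 15.72 to 16.21 and on the right the lactate-limited arrays at 13.72 and 14.14.

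The lactate-limited group was higher than each other group for 48 genes, 30 of them in 5 runs, and the ammonium-deprived group for 21 genes, 15 of them in 1 run. The highest such count in 100 simulations without effects was 1, which bears on false calls only. By limma, 0 genes were lower in the lactate-limited or the ammonium-deprived group than in each other group, and 0 were higher or lower in the fumarate-limited group than in each other group. The numbers of genes at an unadjusted p under 0.05 were 314, 587 and 364 in the comparisons of lactate-limited with fumarate-limited, ammonium-deprived with fumarate-limited and ammonium-deprived with lactate-limited chemostats. The run DSY1709 to DSY1718 lay at 13.72 and 14.14 in the lactate-limited arrays, at 10.09 to 11.15 in the fumarate-limited, at 9.33 to 9.66 in the ammonium-deprived and at 8.58 and 8.60 in the batch arrays. In 10000 shuffles of the calls over the tags, no comparison reached its observed number of tags in runs, and each p was 0.0001, the smallest the shuffles can give. The shuffles take neighbouring tags as independent. Neighbours that vary together for any reason would give runs, so this p does not bear on the culture conditions.

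Few of the 1136 regions changed. On the Y51 chromosome, coordinates as in the deposited table, the region from 587874 to 588221 (348 bases) fell by 3.25 (SE 0.47, limma adjusted p 0.0303) in lactate-limited and by 3.39 (SE 0.43, limma adjusted p 0.0091) in ammonium-deprived chemostats against batch. The region from 328324 to 328927 fell by 3.95 (SE 0.63) in ammonium-deprived chemostats against batch. In the same comparison the regions from 2492023 to 2492522 and from 4381495 to 4382400 rose by 1.75 (SE 0.31) and 1.92 (SE 0.30). These were all the regions past the threshold, and they were chosen after their values were seen. In the other 4 comparisons limma called 0 regions, with 77, 23, 93 and 71 at an unadjusted p under 0.05.

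The genes were not spread evenly in level along the locus tags. Over DSY0864 to DSY1086, a stretch chosen after its values were seen, the running median over 21 tags stayed below 8 on the log2 scale, and it did so nowhere else. The 211 tags measured there had a median level of 7.08, with 6.01 and 9.07 as the 5th and 95th percentiles, against 10.49 for the other genes and 7.34 for the regions. Of these tags, 92.4% stayed below 10 in all 10 arrays, against 15.5% of the other genes. The means of DSY0900 (12.56) and DSY1030 (10.73) lay above the median of the other genes. Of the 211 tags, 1 changed in at least 1 comparison (0.474%), against 910 of the other genes (19.7%).

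**Figure D5:**
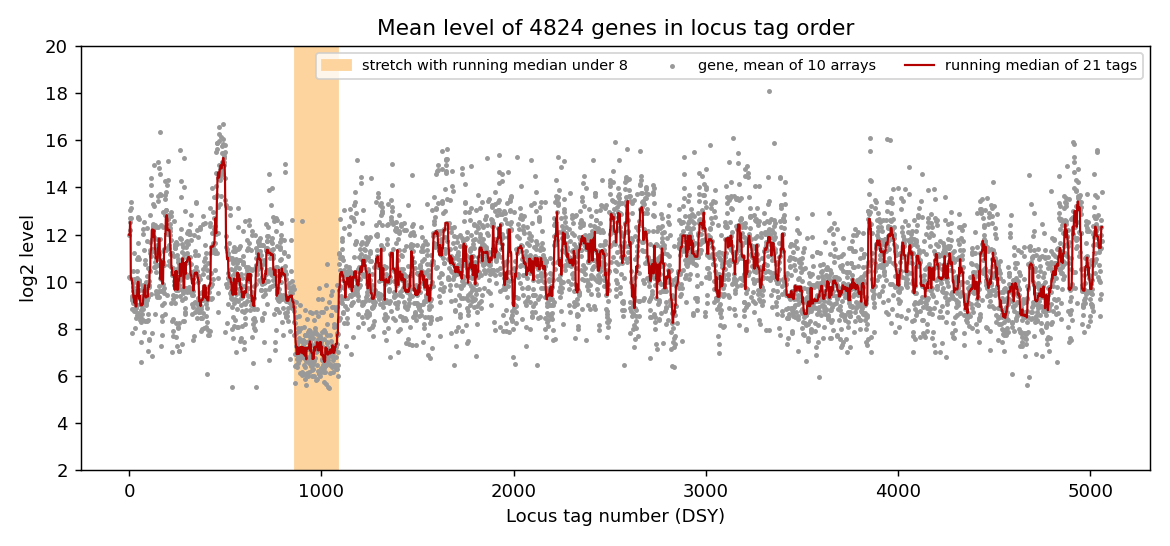
Mean log2 level over 10 arrays (y axis) of each of 4824 genes by locus tag number (x axis), with grey points for genes, a red line for the running median of 21 tags and shading for the stretch whose running median is under 8. The shaded stretch, DSY0864 to DSY1086, has a median level of 7.08 against 10.49 for the other genes.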

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

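Chosen only after the results were seen were the tests of a common shift of dim arrays, in both directions, of dim arrays against batch and of a label swapped with another group. So were the correlation of dim with bright differences and the count outside the long run. The other tests in this part had their outcome rules written before their results were seen.

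Signals appeared in data that the comparisons above left out. Of the 3292 regions that share 1 start, 29 changed between fumarate-limited chemostats and batch (limma, of 379 at an unadjusted p under 0.05), 20 between lactate-limited chemostats and batch (of 224) and 39 between ammonium-deprived chemostats and batch (of 455). Between chemostats, 3 were lower in ammonium-deprived than in lactate-limited ones (limma, of 260 at an unadjusted p under 0.05). Lactate-limited and ammonium-deprived against fumarate-limited chemostats each gave 0 (of 93 and 430). The median level of the 3292 regions was 7.30, near the 7.34 of the regions with a start of their own. The positions of these 3292 regions are unknown, because the printed ends mostly count up by 1 base. No explanation was tested for these changes.

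One gene moved in opposite directions in 2 kinds of chemostat. DSY3101 fell by 1.65 (SE 0.48, limma adjusted p 0.0496) in fumarate-limited chemostats against batch and rose by 2.81 (SE 0.53, limma adjusted p 0.0119) in lactate-limited ones. The direct comparison gave a difference of 4.45 (SE 0.48, limma adjusted p 0.00123). Its fall in fumarate-limited chemostats lay just inside the threshold.

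Ammonium-deprived replicate 1 lay apart from replicates 2 and 3, which were both dim. Noise of dim spots is argued against: among the 1206 genes with the highest level, replicate 1 differed from the others 2.17 times as much as these differed from each other (95% bootstrap interval over genes 2.01 to 2.35). A common shift of dim arrays is argued against for the 146 genes at least 4-fold higher in replicates 2 and 3, of whose median change the dim fumarate-limited replicate 3 showed -10.9%, while for the 257 genes at least 4-fold lower it showed 40.9%, so dimness may account for part of these. Fumarate-limited replicate 3 lay lower over all genes, with a median difference of -0.29, and less the medians of all genes the shares were 0.149% and 33.9%. A label swapped with another group is argued against for the long run. Of its tags, 15 were higher in all 3 comparisons of a fit without replicate 1. Their median in replicate 1 lay 6.37 log2 units above the highest of the 7 other arrays, which ranged over 1.51. The bounds of the run came from the fit with replicate 1. Without replicate 1, limma called 16, 16 and 15 of its 16 tags against fumarate-limited, batch and lactate-limited arrays. A culture outside the 4 groups cannot be told apart, since of 74 genes higher in replicates 2 and 3 than in each other group 37.8% were higher in replicate 1 than in all 7 arrays (chance 12.5%). These were all 15 in the long run and 13 of the 59 outside it (22.0%). The 12.5% holds for genes not chosen by these arrays. The 74 genes were chosen as low in the 7 arrays, so their share by chance can lie above it and is not known. Nor can the different fumarate feed of replicate 1 be told apart, with 1 array at that feed.

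The chemostats lay apart from batch, and both batch arrays were on slide 2. A difference between slides is argued against as the whole cause for fumarate-limited and ammonium-deprived chemostats. The 912 genes called from the slide 1 chemostat arrays against batch moved in the same direction on the slide 2 chemostat arrays. These arrays shared the slide with batch and showed 121% of the median change. This test shares the batch arrays between both sides, which favours a change in the same direction. Fumarate-limited replicate 3 and ammonium-deprived replicate 3, both on slide 2, were dim, so the 121% can hold a part from dimness. Slide 2 held no lactate-limited array, so the test does not cover lactate-limited chemostats against batch. No lactate-limited array was among the 3 dimmest. Their 75th percentiles of green spot intensity, 1174 and 1372, still lay below the 2842 and 3128 of batch, and dimness was not tested for that group. For the other 2 groups, genes were chosen as at least 4-fold different between the 3 dim arrays and 1 batch array. Their change was measured in the 3 bright arrays against the other batch array, both ways round. These bright arrays include fumarate-limited replicate 2, at 1240. Dimness is argued against as the whole cause, since at least 73.8% of the median change was seen for genes higher in chemostats (lowest 95% bootstrap bound 67.5%) and 52.1% for genes lower in them (48.4%). The bound against it was first 50% and was set to 25%, under which dimness would be the whole cause, after these values were seen. A part of the change stays open to dimness. The way of growing, which the design names, stays open as well. It goes together with differences in feed on every chemostat array but fumarate-limited replicate 2. That 1 array had the medium of the batch cultures, 25 mM fumarate and 20 mM lactate. It lay at -2.41 on the first principal component, against 67.5 and 74.8 for batch.

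The comparison of ammonium-deprived with fumarate-limited chemostats is the only one with 3 arrays in each group. The real grouping gave 24 genes, and 2 of the 10 splits of these 6 arrays gave as many, the real one included. The highest of the other splits gave 267, which sets the bright arrays fumarate-limited replicates 1 and 2 and ammonium-deprived replicate 1 against the 3 dim ones. With 10 splits no share under 0.05 can be reached. A split with several times the real count points to a structure of the arrays. Of the 267 genes, 231 were higher in the bright arrays, so for these a shift common to dim arrays may play a part, although over all genes the differences of the dim arrays from the bright ones in the 2 groups correlated at 0.0262. The split cuts across the slides, and with slide as a fixed block the real grouping gave 24 genes.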

How the results depend on the processing

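Chosen only after the data were seen were the scalings of the deposited table, leaving out the 3 dimmest arrays, array weights and the limit to genes above the median level. The gene list tests and the genes fixed by name were not run, because the files do not pair locus tags with names.

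Over 378 refits of the 22 named gene and comparison pairs, each kept its direction in all, and 361 stayed past the threshold. Of the 17 that did not, 7 were DSY0565 (ammonium-deprived against fumarate-limited) and 6 DSY0226. The named genes were chosen as the largest changes in these same arrays, so a kept direction was nearly fixed in advance. All these refits used the deposited table. The scanner probes name no gene, so the named genes were not refitted with another signal, background correction or filter. Counts below follow the order fumarate-limited, lactate-limited and ammonium-deprived against batch, then lactate-limited and ammonium-deprived against fumarate-limited, then ammonium-deprived against lactate-limited. The intensity trend, slide as a random block and the 3 scalings of the table moved no total count by over 1.5 times, but 75th percentile scaling changed the genes higher in fumarate-limited chemostats than in batch from 193 to 326. The cause was not tested for any change given here, those with fewer arrays or genes in the fit included.

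Leaving out 1 array, the ranges were 29 to 656, 78 to 257, 67 to 1047, 32 to 66, 22 to 367 and 65 to 247. Leaving out a batch or lactate-limited array leaves a lone array assumed to vary like the other groups. Without batch replicate 1 the first 3 counts were 82, 111 and 123, and without batch replicate 2 they were 29, 85 and 67. Without ammonium-deprived replicate 1 its comparisons gave 1047, 367 and 247. Against batch, ammonium-deprived gave 196 without replicate 2, 179 without replicate 3 and 197 with these 2 as 1. Without lactate-limited replicate 2 the counts were 78 and 32, and without fumarate-limited replicate 2 the first was 297.

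Slide as a fixed block moved the lactate-limited count to 109. Slide 1 alone gave 0 for lactate-limited against fumarate-limited (limma, 207 unadjusted) and 45 against ammonium-deprived. Slide 2 alone gave 242, 279 and 76 for fumarate-limited and ammonium-deprived against batch and against each other. Slide 1 has 1 fumarate-limited and slide 2 has 1 ammonium-deprived array, assumed to vary like the other groups. Fits of 2 groups alone gave 387 and 979 for fumarate-limited and lactate-limited against batch, and 29 against each other.

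Without the 3 dimmest arrays the first 5 counts were 1094, 1041, 394, 205 and 42, with 394 and 42 from a lone ammonium-deprived array assumed to vary like the other groups. Array weights gave 1844, 1303, 2145, 184, 1062 and 374. Genes above the median level gave 383, 22 and 47 for ammonium-deprived against batch, lactate-limited against fumarate-limited and ammonium-deprived against lactate-limited.

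The scanner files gave more changed targets for lactate-limited against batch: 553 as designed, 594 with gProcessedSignal and 556 with the median of probes. They test 7776 targets, not 4824 genes, and 553 is 7.11% against 6.53% in the table. With gProcessedSignal ammonium-deprived against batch gave 961. With median scaling fumarate-limited and ammonium-deprived against batch gave 1060 and 1135, and against each other 15. With no filter 240, 313, 26 and 15 changed, in all but the lactate-limited comparison with batch and the last. With probes well above background on all 10 arrays, 942, 700, 922, 29, 12 and 48 of 3852 targets changed. Signal over background limits the 3 dimmest arrays most.

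With the replicate number as a block the counts were 452, 344, 412, 56, 24 and 83. Deviations of the 13 pairs of same-numbered arrays correlated at -0.35 to 0.21, with 5 pairs over 0.1. Pairs with different numbers were not taken as a reference. In groups of 2 arrays the deviations mirror each other, so the pairs are not independent. Whether the numbers pair the arrays therefore cannot be told.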

Other observations

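Chosen only after the results were seen were all tests of this part, which reports nothing planned.

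The stretch DSY0864 to DSY1086 lay near the level of the regions in each of the 10 arrays. In 200 shuffled tag orders the longest such stretch held 5 tags (p 0.00498, the smallest these shuffles can give). An origin in the processing of the table is argued against for the tags from DSY0905 on. By their values, DSY0905 and DSY1093 followed the scanner targets SH1647 and SH1780. The 264 probes numbered between these were well above background in 24.9% of probes and arrays, 29.0% of the share in flanking probes (85.9%). That these probes face the stretch is inferred from target numbers. Inside the stretch 4 tags were matched, DSY1032 and DSY1036 to the same target. The targets next below SH1647 were in neither set of probes. Genes missing from the cultured cells and genes present but silent in all 4 groups cannot be told apart, since RNA alone does not part them and DNA of the cultured cells would. Of the tags, 0.474% changed in any comparison and 7.58% passed 10 in at least 1 array, with means of 12.56 for DSY0900 and 10.73 for DSY1030. The design names no difference between cultures that bears on a stretch low in all 4 groups.

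DSY4254 to DSY4257, a run of 4 tags higher in lactate-limited chemostats, lies directly before the run of 16 tags that was higher in ammonium-deprived chemostats. Its median change was 5.45 in lactate-limited chemostats against batch and 0.18 in ammonium-deprived ones, with 4 and 0 tags past the threshold. The neighbouring runs thus changed in different groups.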
